A study of Mus musculus with 2 samples.

How the data were processed

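H3K4me2 chromatin immunoprecipitation was followed by sequencing in whole lung of B6NCrl mouse embryos at embryonic day 16.5, in 2 biological replicates of 1 group. Both replicates are separate biological samples per the labels, which also say that male and female tissue was pooled. The reads were processed by the ENCODE consortium, and what was used here are its peak lists on build mm10.

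Per the description deposited with each sample, replicate 1's list and the pooled list were derived from filtered alignments and 2 further files whose kind is not given, and replicate 2's list from its alignments and 1 such file. The replicated list was derived from the pooled list and both replicate lists, by a rule that is not given in the sources used here. The aligner and the peak caller are likewise not given in the sources used here. The signal value of each peak is the authors' own, in a unit the deposited description does not name, and it was used only to rank or describe peaks within a list. The -log10 p and -log10 q of each peak are the authors' values in the deposited lists, and -log10 q was used as a filter of at least 5 in alternatives. The fixed plan had assumed a fold in the column of signal values, and the signal was used in its place for ranks. Positions are the authors' peak boundaries in bp, printed counting from 1. The lists give no counts, so depth, counting intervals and sampling noise could not be had, and precision was judged from the replicates alone.

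The reference was GRCm38 with the GENCODE M21 annotation, the same sequence as mm10, and no peak ran past a chromosome end. Of the annotation, 21829 protein-coding gene symbols with 54355 TSSs were used, on chromosomes 1 to 19, X and Y, and 27 symbols with more than 1 gene identifier were merged. Peaks on other contigs (14 of the replicated list) were left out of all comparisons. Promoters were the 1 kb either side of a TSS, a peak touching none was distal, and the class of a distal peak was exon before intron before intergenic. Domains were replicated peaks joined over gaps of up to 1 kb, and a gene took the widest domain at its promoters. A distal peak was given to the gene of the nearest protein-coding TSS within 100 kb. Peaks touching no promoter stayed distal even where they were joined into a promoter's domain.

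Replicate overlap required at least 50% of a peak's own length in the other list. Its null, and that of the promoter share, were 100 seeded circular rotations of a list along each chromosome (one-sided). The 25 gene lists came from textbook knowledge, and 12 genes stand in more than 1 list, all except Prox1 in the signalling list. They were tested in 3 ways, each adjusted by Benjamini-Hochberg over the lists with a threshold of 0.05: marking by Fisher's exact test (two-sided), width against 10000 random lists of marked genes, and distal peaks against 10000 random lists matched on deciles of the sequence length nearest to a gene. Of the genes in the lists, Dnai1 was missing from the annotation. The 13 motif families were searched as consensus sequences on both strands, against windows 10 kb away outside all pooled peaks, with Mantel-Haenszel odds ratios over GC deciles. CpG observed over expected was taken in the 1 kb either side of a TSS, and each gene took the highest value among its TSSs.

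Genes were named by a rule: 19 anchor genes whatever their values, the 3 widest and up to 3 unmarked members of each list past the threshold in any test, the 10 genes with the widest domains, the 5 with the most distal peaks, the nearest genes of the 5 peaks of highest signal, and up to 10 list members marked in 1 replicate. The lists, tests, this rule and 56 alternatives were fixed before the data were examined. A further 6 alternatives were chosen after seeing the data: shuffled motif letters that keep the number of CpG steps, genes whose promoter overlaps no other gene's, replicated peaks that touch both replicate lists, widths matched on the number of TSSs, the exact conditional test over CpG deciles, and Hox domains counted once each. That exact test was chosen with the planned Mantel-Haenszel result already seen, and both are reported.

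The list tests were tested on 1 simulated data set with 40 changed and 160 unchanged lists, drawn from the 21829 genes. The changed lists were drawn from 1 pool of altered genes, so they overlap and are not 40 separate trials. The marking test called 39 of the changed and 2 of the unchanged lists, the exact test over CpG deciles 39 and 2, the Mantel-Haenszel test 32 and 2, the width test 38 and 0, and the distal test 31 and 1. Simulated marking did not follow promoter CpG, as real marking does, so these counts cannot rank the CpG tests on the real lists. Simulated domains were not joined over gaps, and simulated distal peaks did not depend on the sequence length nearest to a gene. In the distal test, 6.875% of the unchanged lists had a permutation p under 0.05 before adjustment. Interval overlaps were checked against a brute-force count with 0 disagreements. The computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.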

Results

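The histone mark H3K4me2, dimethylation of lysine 4 on histone H3, lies at promoters and enhancers that are active or poised, and it was mapped by chromatin immunoprecipitation and sequencing in whole lung of mouse embryos. The tissue was taken on embryonic day 16.5 from animals of the B6NCrl strain, with male and female tissue pooled. There was 1 group with 2 biological replicates, and the labels give a pool of 41 embryos for replicate 2 and no number for replicate 1. The data were 4 lists of peaks on mouse build mm10: 1 per replicate, 1 called on both replicates pooled, and 1 of replicated peaks. On chromosomes 1 to 19, X and Y, replicate 1 had 58425 peaks over 50.9 Mb and replicate 2 had 48610 peaks over 40.9 Mb. The lists hold no read counts, so the depth behind each peak is unknown. Genes and regions are not independent replicates, so p-values across them describe these lists and not other litters.

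Most of the lung genes chosen in advance carried the mark at their promoters, as 67.5% of all protein-coding genes did. The promoter of Nkx2-1, the master transcription factor of lung epithelium, carried a replicated domain of 4805 bp (chromosome 12, 56534508 to 56539312) that measured 6808 bp in replicate 1 and 4600 bp in replicate 2. The surfactant genes Sftpc and Sftpb carried domains of 7188 bp and 2814 bp, although the Sftpc domain also covers the start of its neighbour Bmp1. The mesenchymal factors Tbx5 and Foxf1 had domains of 20102 bp and 18294 bp, and Tbx4, which acts with Tbx5 in lung budding, had 9251 bp. Fgf10, the mesenchymal signal for branching, had 6726 bp, and Sox9 of the distal epithelial tips had 7119 bp against 1973 bp for Sox2 of the proximal airway. Scgb1a1, the secretory product of club cells, and Alb, the serum albumin of liver, had no peak at their promoters in any replicate. Among the other anchors from outside the lung, Nkx2-5 of heart and Neurod1 of neurons were marked, and Myod1 of muscle had no replicated peak.

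The comparison the design itself gives is replicate against replicate. Of replicate 1's peaks, 34955 (59.8%) had at least 50% of their length covered by a peak of replicate 2, and 42489 (87.4%) of replicate 2's peaks were covered by replicate 1. Random rotation of the other list along each chromosome covered 1.56% and 1.94% on average, and the one-sided permutation p of 0.0099 for each is the smallest that 100 rotations can give. The lists shared 38.3 Mb of the 53.5 Mb covered by either, or 71.6%. In the weakest decile of replicate 1's peaks by the authors' own signal value, 12.1% were matched, against 100% of 5843 peaks in the strongest. In replicate 2 the same deciles gave 56.8% and 100%. The list of replicate 1 was derived from a further input file that replicate 2's was not, so the difference in peak number is not a measure of the tissue.

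**Figure D1:**
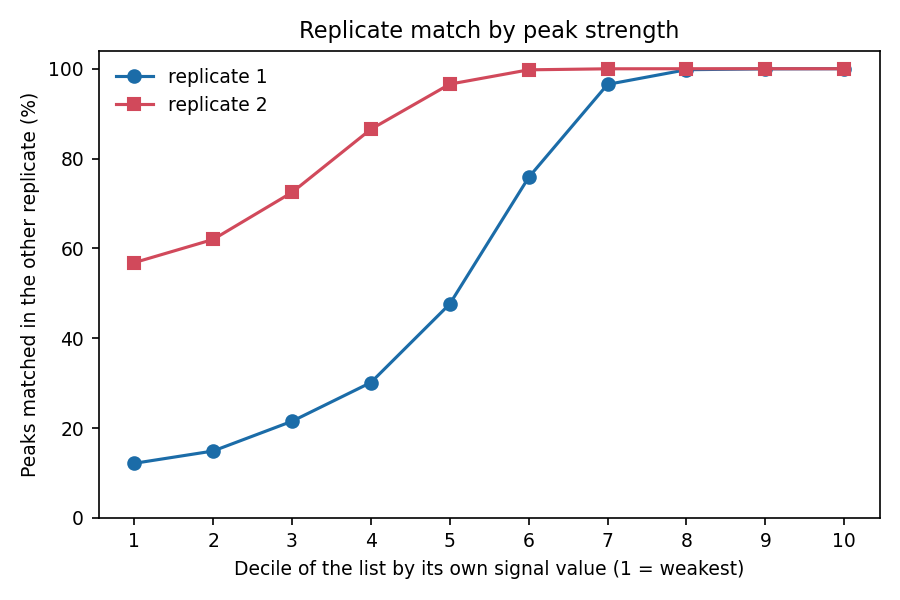
Percent of peaks of each replicate with at least 50% of their length in the other replicate's list (vertical axis), by decile of the list's own signal value (horizontal axis, 1 weakest), with 1 point per decile and replicate. Replicate 1 rises from 12.1% to 100% and replicate 2 from 56.8% to 100%.

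Matched and unmatched peaks lay in different parts of the genome. In replicate 1, 53.8% of the matched peaks and 9.0% of the 23470 unmatched peaks overlapped a promoter. In replicate 2 the shares were 50.6% and 9.03%, the latter of 6121 peaks. Matched peaks were also wider, with medians of 991 bp against 258 bp in replicate 1 and 683 bp against 212 bp in replicate 2. Fisher's exact test of the promoter share gave odds ratios of 11.8 and 10.3, with p-values too small for the software to represent. Among genes, 14632 had a promoter peak in both replicates, 285 in replicate 1 only and 58 in replicate 2 only. The 442 genes of the lists other than sensory receptors included 19 seen in 1 replicate, such as the endothelial cadherin Cdh5, the muscle factors Myod1 and Myf5, and Lamp3 of alveolar type 2 cells, each in replicate 1 only.

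All 43192 replicated peaks were also in the pooled list, where they made up 81.3%. Only 34807 pooled peaks (65.5%) had at least 50% of their length covered by both replicate lists. Of the replicated peaks, 37648 touched both replicate lists, 4862 touched only replicate 1's, 521 only replicate 2's and 161 neither. These 5544 peaks (12.8%) were weaker, with a median signal of 3.79 against 13.5 for those seen in both lists. The rule behind the replicated list also works the other way at named genes. The collagen gene Col3a1 and the endothelial gene Vwf had a promoter peak in each replicate's list and none in the replicated list.

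Promoters held a far larger share of peaks than random placement gave. Of the 43192 replicated peaks, 19511 (45.2%) overlapped the 1 kb either side of a protein-coding transcription start site (TSS), against 3.83% after rotation (ratio 11.8, permutation p by rotation = 0.0099, one-sided, the smallest possible). The ratio was 16.02 within 500 bp and 7.38 within 2500 bp. The remaining 23681 distal peaks fell in introns (23.8% of all peaks), between genes (26.8%) and in exons (4.2%). Promoter peaks were wider, with a median of 1440 bp against 467 bp in introns, and held 67.5% of the covered bases. The replicates' own lists gave 35.8% and 45.4% at promoters, a mean of 40.6% ± 6.74 (SD, n = 2). The 5 peaks of highest signal lay over the start of the long noncoding RNA Lncpint (chromosome 6, 31215955 to 31219018, signal 72.7), at the promoters of Rasgef1c, Gnal and Spdya, and over the start of a transcript of Aff1 that is not annotated as protein-coding.

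A gene was called marked when a replicated peak lay within 1 kb of one of its TSSs, which held for 14737 of 21829 protein-coding genes (67.5%). The replicates' own lists gave 68.3% and 67.3%. Lists of lung lineage genes, and lists of other organs and blood for comparison, were tested against all other genes. Of the 25 lists, 8 were marked more often and 8 less often at an adjusted p under 0.05 (Fisher's exact test, two-sided, Benjamini-Hochberg over the lists).

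Distal progenitor, signalling and alveolar type 1 genes were all marked. All 23 distal progenitor genes were marked (adjusted p = 0.000545, Fisher's exact test), among them the transcription factors Irx2, Foxa2 and Etv5. So were all 40 genes of the signalling pathways of lung growth (adjusted exact p = 1.19e-06), including Shh and its receptor Ptch1, and all 16 alveolar type 1 genes (adjusted exact p = 0.0056), including Vegfa and the caveolar protein gene Cav1. The mesenchyme list had 27 of 28 marked (adjusted exact p = 0.00104), the exception being Col3a1. The endothelium list had 25 of 26 (adjusted exact p = 0.0027), with Fli1, Lyl1 and Gata2 among the widest and Vwf unmarked. All 26 housekeeping genes were marked, including Eef2 and Polr2a, as were 17 of 18 Hox genes of groups 1 to 6. A list of brain genes also stood high, with 19 of 20 marked (adjusted exact p = 0.0134), among them Bcl11b and Pax6. With 1 TSS per gene neither the anterior Hox list (adjusted exact p = 0.409) nor the brain list (0.0989) passed. The anterior Hox list also fell short without sensory receptors among the other genes (adjusted exact p = 0.0546).

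The 8 lists marked less often were of immune, liver, red cell, skeletal muscle, gut, germline, keratinocyte and sensory genes. Of 20 immune genes, 2 were marked, Ikzf1 and Pax5, while Cd19, Cd3e and the macrophage gene Adgre1 were not (adjusted exact p = 1.19e-06). The liver list also had 2 of 20, Prox1, which is shared with the endothelium list, and Apoa1. The red cell list had 4 of 14, with Epor, Klf1 and Gypa marked and the haem synthesis gene Alas2 unmarked. Skeletal muscle had 6 of 16 (adjusted exact p = 0.025, and 0.258 in replicate 1's list alone), with Mylpf (whose domain also covers the start of Tbc1d10b), Ryr1 and Pax3 marked and the muscle creatine kinase gene Ckm unmarked, and intestine and pancreas had 7 of 18. Germline and pluripotency genes had 4 of 20 (Ddx4 and Figla unmarked), terminal keratinocyte genes 1 of 12 (Krt10), and the sensory receptor families 8 of 1498. The Fisher exact adjusted p-values of these lists ran up to 0.0311, for intestine and pancreas, which did not pass in the pooled list (0.0649) or in a window of 2500 bp (0.0606). Skeletal muscle did not pass with 1 TSS per gene (adjusted exact p = 0.0549).

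The other 9 lists did not pass the test, though smooth muscle and pericyte (adjusted exact p = 0.0715) passed in a window of 500 bp (0.044). They were alveolar type 2 (13 of 18 marked), proximal airway (11 of 20), neuroendocrine (11 of 13), smooth muscle and pericyte (14 of 15), mesothelium (6 of 11), peripheral nerve (9 of 12), heart (12 of 18), kidney (7 of 14) and Hox groups 9 to 13 (11 of 16). In the alveolar type 2 list Sftpc, Muc1 (whose domain also covers the start of Mtx1) and Cebpa were marked, and Lyz2, Lcn2 and Chia1 were not. In the neuroendocrine list Ascl1, the factor that specifies these cells, Insm1 and Nkx2-2 were marked, and Ddc and Resp18 were not. Foxj1, the regulator of motile cilia, was marked with a domain of 3283 bp.

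Marking followed the CpG content of promoters, and this changed which lists stood apart. Marked genes had a median CpG observed over expected of 0.624 against 0.177 in unmarked genes, and the marked share went from 1.33% in the lowest CpG decile to 99.6% in the highest. When members were compared with other genes of the same CpG deciles (Mantel-Haenszel test), 3 lists were higher and 4 lower. Alveolar type 2 genes then stood high, with 72.2% marked where 43.8% were given by CpG content, as did smooth muscle and pericyte genes (93.3% against 59.8%) and endothelial genes (96.2% against 70.5%). Germline genes stood low (20% against 70.9%), as did immune genes (10% against 39.4%), sensory receptors (0.534% against 10.2%) and Hox groups 9 to 13 (68.8% against 96.1%). Because the Mantel-Haenszel test is approximate for lists this short, an exact conditional test was chosen after its result was seen. It gave 4 higher and 6 lower, keeping those 7 lists (adjusted exact p = 0.000595 for alveolar type 2, 0.00607 for smooth muscle and pericyte, 0.000187 for endothelium, 3.58e-09 for germline, 0.000719 for immune and 0.000155 for Hox groups 9 to 13). It added alveolar type 1 (adjusted exact p = 0.0269), liver (0.0269) and terminal keratinocyte genes (0.0149). The distal progenitor, mesenchyme, signalling, brain, housekeeping and anterior Hox lists passed neither (adjusted p of 0.151 and above in the exact test). All progenitor, signalling and housekeeping genes were marked, where CpG content gave 93.7%, 94.8% and 97.3%. No higher count was possible for these lists, so the test could not have called them higher and cannot decide the matter. Of the lists marked less often, red cell (28.6% marked where 31.6% were given by CpG content), skeletal muscle (37.5% and 46.8%) and intestine and pancreas (38.9% and 50.1%) passed neither, with adjusted exact p of 1, 0.659 and 0.303.

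**Figure D2:**
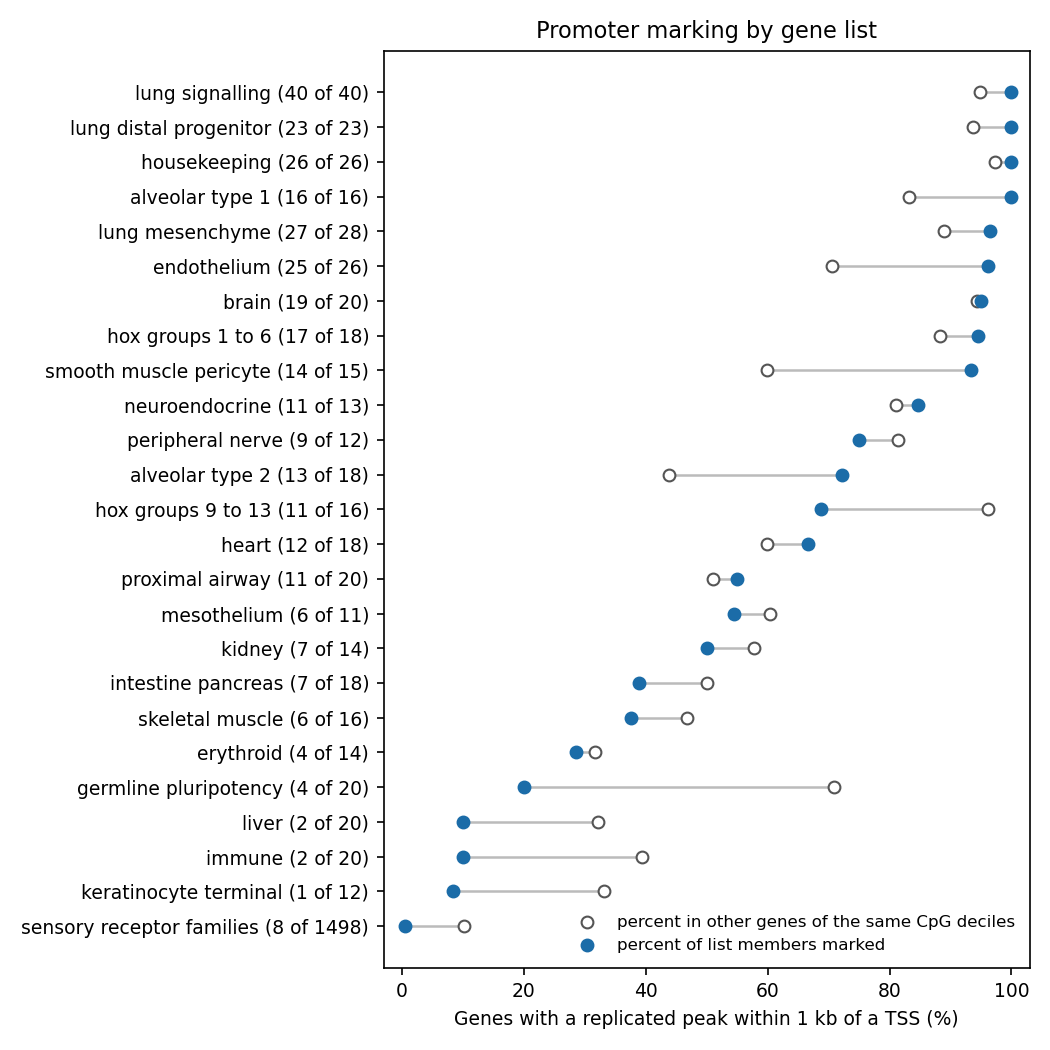
Percent of each gene list with a replicated peak within 1 kb of a TSS (filled points) and the percent marked among other genes of the same promoter CpG deciles (open points), for 25 lists with the number marked and tested in brackets. The lists run from 0.534% in the sensory receptor families to 100% in 4 lists, and Hox groups 9 to 13 lie at 68.8% where their CpG deciles give 96.1%.

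Domains were wide at distal progenitor, mesenchyme and signalling genes, and less so at endothelial and alveolar genes. Replicated peaks joined over gaps of up to 1 kb formed domains, and the domain at a marked gene had a median width of 2322 bp. The distal progenitor list had a median of 6777 bp (2.92 times that of random marked genes), mesenchyme 6726 bp (2.9 times) and signalling 6230 bp (2.69 times). The signalling list is not separate from the other 2: its 3 widest members were Ptch1 of the mesenchyme list and Shh and Fgfr2 of the progenitor list. Endothelium had 4219 bp, alveolar type 1 had 3988 bp and alveolar type 2 had 3851 bp. The widest members were Irx2 (15332 bp), Foxa2 (14574 bp) and Etv5 (12385 bp, but 5797 bp in replicate 2) in the progenitor list. In mesenchyme they were Tbx5, Ptch1 (19535 bp) and Foxf1, and in endothelium Fli1 (8412 bp), Lyl1 (7428 bp) and Gata2 (6669 bp). In alveolar type 1 they were Vegfa (7061 bp), Cav1 (6639 bp) and Gprc5a (5755 bp).

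Marked genes of heart, skeletal muscle, gut, germline, nerve, brain and the neuroendocrine lineage of the lung had narrow domains. The 12 marked heart genes had a median of 962.5 bp, with the cardiac regulators Nkx2-5 at 431 bp and Gata4 at 2246 bp (3767 bp in replicate 1 and 1129 bp in replicate 2). Skeletal muscle had 1025.5 bp, intestine and pancreas 826 bp, germline 1183 bp, peripheral nerve 1509 bp, brain 1716 bp and neuroendocrine 1481 bp. The neuronal factor Neurod1 had 553 bp, and Ascl1, the widest of the neuroendocrine list, 2769 bp. The 8 marked sensory receptor genes had a median of 580.5 bp, and Hox groups 9 to 13 had 840 bp.

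Against 10000 random lists of marked genes, 7 lists were wider and 9 narrower (two-sided permutation p, Benjamini-Hochberg over 22 lists). The progenitor, mesenchyme, signalling, endothelium, alveolar type 1 and anterior Hox lists each had the smallest permutation p that the draws allow, 0.0002 (adjusted p = 0.00055), and alveolar type 2 had an adjusted p of 0.0064 that rose to 0.0528 without joining peaks. Of the narrow lists, heart had an adjusted permutation p of 0.00055, and 4 were lost under other settings: peripheral nerve (main adjusted p = 0.0467), brain (0.0372), germline (0.0372) and neuroendocrine (0.0294). Brain turned to the wide side with a gap of 3 kb (adjusted permutation p = 0.579). Smooth muscle and pericyte (3050.5 bp), housekeeping (2811 bp), mesothelium (2243 bp), proximal airway (1973 bp), kidney (1760 bp) and the red cell list (1565.5 bp) did not pass. Against random lists matched on promoter CpG, smooth muscle and pericyte genes were wider (1.81 times, adjusted permutation p = 0.00474). With a gap of 3 kb, however, housekeeping (adjusted permutation p = 0.0108) and smooth muscle and pericyte (0.0167) were wider too, as in the pooled list (0.0113 and 0.00711) and in replicate 1's list alone (0.00275 and 0.00055). In replicate 2's list alone neither passed (adjusted permutation p = 0.0694 and 0.776), and smooth muscle and pericyte genes had a median of 2067.5 bp against 4397.5 bp in replicate 1. Proximal airway genes were narrower in replicate 1's list alone (1344 bp, adjusted permutation p = 0.00275) and not in replicate 2's (0.23). The immune, liver and terminal keratinocyte lists had fewer than 3 marked members and were not tested for width.

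**Figure D3:**
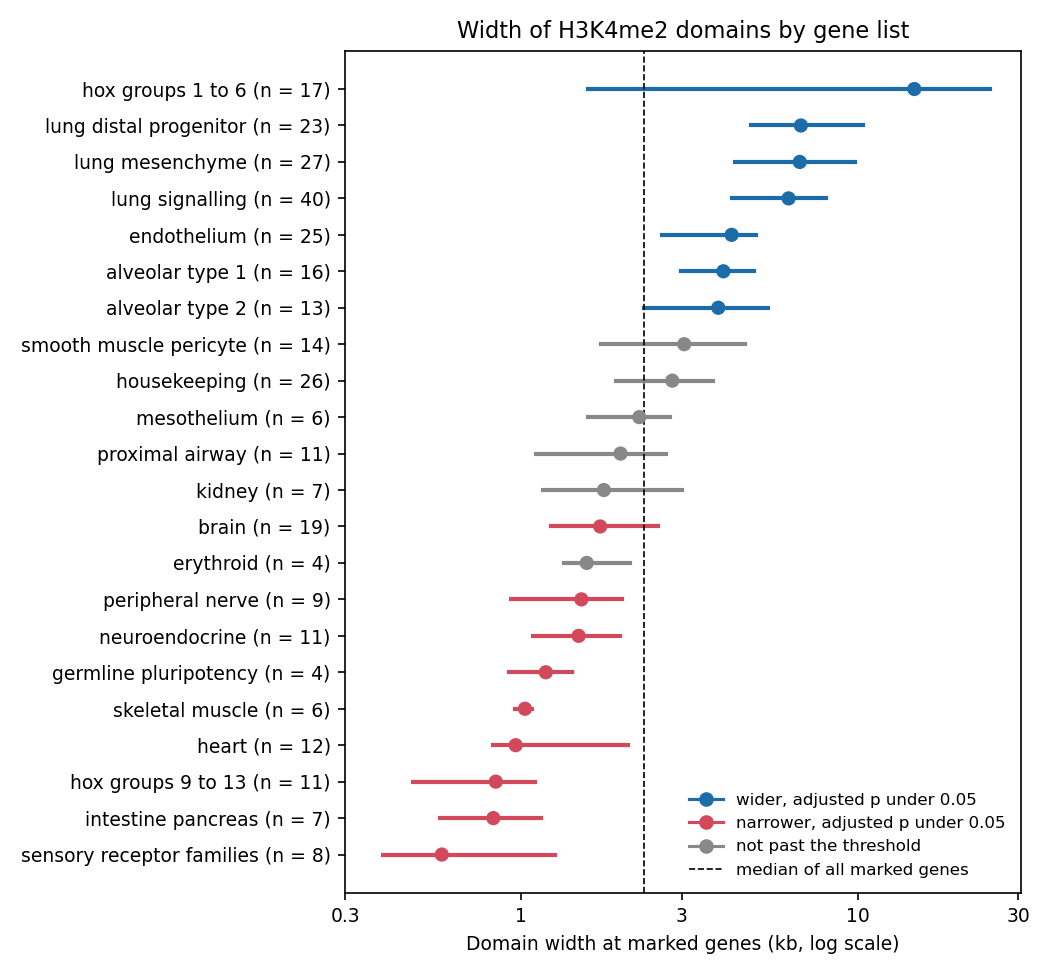
Median domain width at marked members of each list (points, kb on a log axis) with the lower to upper quartile (bars), for the 22 lists with at least 3 marked members. The dashed line is the median of all marked genes, 2322 bp, and the lists run from 580.5 bp in sensory receptors to 14730 bp in Hox groups 1 to 6.

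The single widest domain over a TSS spanned Hoxb3, Hoxb4, Hoxb5 and Hoxb6 (chromosome 11, 96298555 to 96346581, 48027 bp, 3 peaks), and measured 56922 bp in replicate 1 and 31763 bp in replicate 2. It was followed by Nr2f2, a nuclear receptor gene (26995 bp), by a domain of 24778 bp over Hoxa1, Hoxa2 and 5730596B20Rik (chromosome 6, 52156822 to 52181599), and by Tbx5 and Nfib (19857 bp). Nfib, a factor needed for lung maturation, also had the most distal peaks of any gene, 32. Its domain joined 9 peaks, and any of these over 1 kb from a TSS count as distal too. In distal peaks Nfib was followed by Mecom with 25, Bach2 with 24, Foxp1 of the lung epithelium with 22 and Gse1 with 21. In the replicates' own lists Nfib had 58 and 37, still the most of these 5, and Gse1 had 37 and 17.

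Distal peaks gathered around progenitor, endothelial, mesenchymal and signalling genes. Distal peaks here include peaks joined into a promoter's domain, so their number is not separate from domain width. The domain of Tbx5, for example, joined 7 peaks. No setting left out all the peaks inside promoter domains. Distal progenitor genes were nearest to 129 distal peaks within 100 kb, 5.61 per gene and 2.92 times that of random lists matched on the length of sequence nearest to each gene. Endothelial genes had 2.93 times, mesenchyme genes 2.7 times, signalling genes 2.44 times, smooth muscle and pericyte genes 2.51 times and alveolar type 1 genes 2.26 times. Tbx5 had 13 such peaks, Fgfr2, the receptor for Fgf10, had 10, Foxa2 and Nkx2-1 had 9 each, and Foxf1 and Cdh5 had 8 each. The annotation of Fgfr2 runs from 130162451 to 133123350 on chromosome 7. Where along it the peaks lie was not examined. The replicates' own lists gave more for Foxa2 (21 and 20), Nkx2-1 (15 and 10) and Fgfr2 (22 and 11), and more in replicate 1 but fewer in replicate 2 for Foxf1 (14 and 7) and Cdh5 (13 and 7). Hox groups 1 to 6 had 4.43 times, from 28 peaks. Sensory receptor genes had 0.0705 times, and 53 peaks among 1498 genes.

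These 7 lists were higher and 1 lower (two-sided permutation p over 10000 random lists, Benjamini-Hochberg over 25 lists). The progenitor, mesenchyme, endothelium, signalling, anterior Hox and sensory lists had the smallest permutation p possible, 0.0002 (adjusted p = 0.000833), alveolar type 1 had an adjusted p of 0.03 and smooth muscle and pericyte 0.0369. The other 17 lists did not pass, among them brain (1.95 times, adjusted permutation p = 0.0572), housekeeping (2.07 times, 0.1), kidney (2.0 times, 0.139) and alveolar type 2 (0.979 times, 1). Alveolar type 1 and smooth muscle and pericyte were lost in several alternatives, with adjusted p up to 0.0931 and 0.11, and the anterior Hox list without matching on territory (0.389).

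Hox genes lie in clusters whose order follows the body axis, and the groups at the 2 ends of the clusters differed in width. Groups 1 to 6 had a median domain of 14730 bp and groups 9 to 13 of 840 bp (permutation p = 0.00179, a test chosen after the widths were seen). The anterior median was 4759 bp without joining peaks, 60751 bp with a gap of 3 kb, 25335 bp in the pooled list, 26024 bp in replicate 1 and 14526 bp in replicate 2. Neighbouring anterior genes share domains, as Hoxb3 to Hoxb6 do, and the 17 marked anterior genes lie on 11 domains with a median of 2025 bp. Counted once each, they were wider than the 11 posterior domains (permutation p = 0.00819, also chosen after) but not wider than random ones (adjusted permutation p = 0.575), so the width of the anterior list rests on a few long domains. Marking itself was 17 of 18 against 11 of 16, a difference of 25.7 points (Fisher's exact p = 0.0782, two-sided). Hoxc6 was the unmarked anterior gene. In the posterior list Hoxb9 (1816 bp), Hoxa13 (1579 bp) and Hoxd9 (1143 bp) were the widest, and Hoxa11, Hoxc11 and Hoxc12 were among the 5 unmarked.

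**Figure D4:**
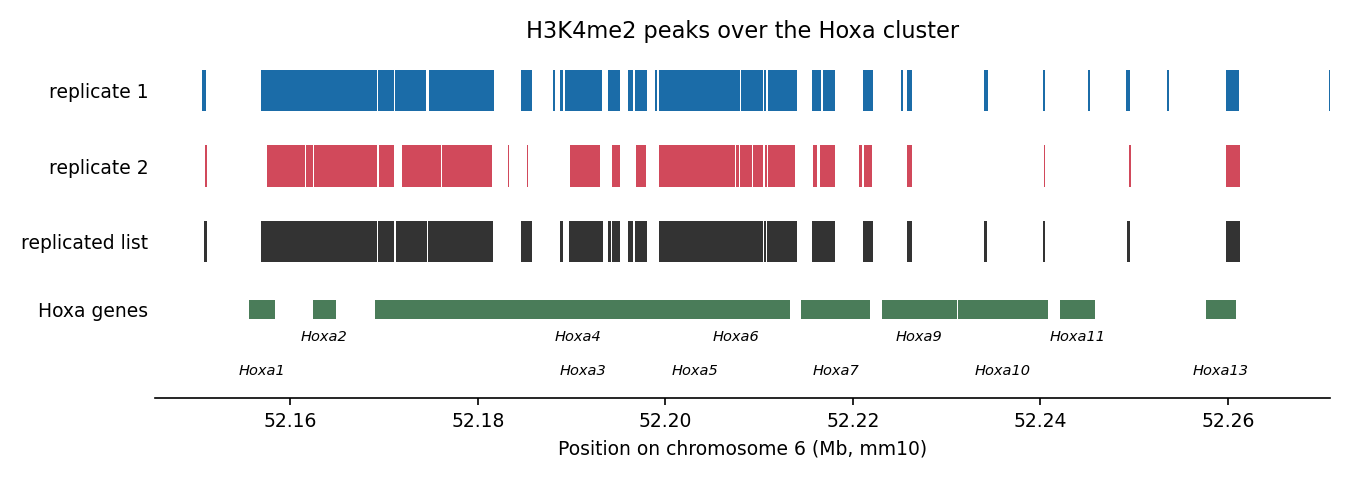
Map of the Hoxa cluster on chromosome 6 (horizontal axis, Mb) with the peaks of replicate 1, replicate 2 and the replicated list as blocks above the spans of the Hoxa genes. Long blocks cover Hoxa1 and Hoxa2 and the stretch around Hoxa5 and Hoxa6 in both replicates, and short ones lie over Hoxa9, Hoxa10 and Hoxa13.

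The X chromosome had fewer peaks than any autosome. It held 6.78 replicated peaks per Mb against an autosomal median of 18.04, a ratio of 0.376, with 0.343 in replicate 1 and 0.4 in replicate 2. The lowest autosome was chromosome 14 with 12.6 and the highest chromosome 11 with 27.4. Promoter peaks on X were at 0.544 of the autosomal median and distal peaks at 0.248. No test was made between 1 chromosome and 19.

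Compared within GC deciles, distal peaks held binding site sequences of several factor families more often than windows of the same length 10 kb away. The 23376 peaks and their windows were compared within GC deciles and not pair by pair. The Mantel-Haenszel odds ratio was 2.02 for CTCF, the insulator protein (95% interval 1.73 to 2.37, 2.96% of peaks, CCASYAGRKGG). It was 1.52 for MEF2, a family of muscle and vascular factors (1.27 to 1.81), and 1.43 for FOX, the family of Foxa2 and Foxf1 (1.36 to 1.51, TRTTTAC, 17.1% of peaks). ETS, the family of Fli1 and Etv5, had 1.35 (1.25 to 1.46), C/EBP, the family of Cebpa, 1.31 (1.14 to 1.5) and GATA 1.13 (1.08 to 1.18). The nuclear receptor site AAGGTCA (0.764, 0.717 to 0.814) and AP-1 (0.921, 0.864 to 0.982) were less frequent. These 8 families passed the adjusted threshold over 13 families, and RFX (1.18), HNF4 (1.11), TEAD (1.0), NKX2 (1.0) and SOX (0.997) did not pass. Median GC was 49.8% in peaks and 44.9% in windows. Without GC deciles, GATA lay in 27.2% of peaks and 30.9% of windows, so its odds ratio over 1 rests on the GC deciles. AP-1 lay in 10.7% and 10.6%, while CTCF, MEF2, FOX, ETS and C/EBP were also more frequent in peaks without them. Against 20 shuffles of each consensus, a comparison chosen after the odds ratios were seen, GATA was exceeded by 3. AP-1 lay above its shuffled median of 0.898 and so was no rarer than its shuffled letters. CTCF, MEF2, FOX, ETS and C/EBP lay above all 20, as did RFX, which had not passed the threshold. All 20 shuffles of the nuclear receptor site lay at or above it.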

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

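Of the tests in this part, 4 were chosen after the result was seen: the signal rank of unmatched peaks, the match of widths on promoter CpG, the X count per gene and the X distal density. The design has 1 group, so no biological explanation was tested for any pattern.

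The replicated list held 14 peaks on 6 contigs outside chromosomes 1 to 19, X and Y, sequence that no comparison used, with a highest signal of 14.8.

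Replicate 1 had 23470 peaks without a match in replicate 2. Of these, 93.1% lay in the lower-ranked part of its list by signal value, split at the median. That restates the rise in matching with signal, so whether they are peaks close to the authors' calling threshold stays open. Wide regions broken up differently stay open, since 28.3% of unmatched peaks lay within 1 kb of a matched one, against 4.32% after rotation and short of the 50% set for that cause. Among unmatched distal peaks 0 of 11 lists of other organs, blood and nerve were raised. Brain (odds ratio 0.385, adjusted exact p = 0.00161) and kidney (0.363, 0.0214) were lower. The test took no account of signal, with which matching rose, and the highest odds ratio, 1.13 for liver, rests on 15 peaks. Tissue of another organ in replicate 1's sample therefore stays open. The unlike input files of the replicate lists and their unknown depths remain untested.

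The wide domains at 7 lists were set against 3 technical explanations. Sharing of 1 domain by neighbouring genes left 6 of the 7 lists wider when each domain was counted once, all except Hox groups 1 to 6. Random lists matched on gene length left 7, and lists matched on promoter CpG left 7, so neither accounts for the pattern. What stays open is the mix of cells in whole lung, where abundant lineages may give wider domains than rare ones, as a hypothesis that no sample here can test.

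Gene number alone did not account for the low density on X, since peaks per gene were still 0.551 of the autosomal median. Per Mb the ratio was 0.376, and the lowest autosome, chromosome 7, had 1.36 peaks per gene against 1.17 on X. Nor did repeats alone, with 0.466 of the autosomal median per Mb outside repeat masking. These factors were not tested in combination. Promoter CpG content stays open for promoters: the percent of X genes marked, minus what autosomal genes of the same CpG deciles gave, was -5.99 points (exact p = 2.03e-08), but chromosome 18 lay at -6.27 and chromosome 14 at -3.99. Without the 34 Rhox genes, none of them marked, X lay at -4.54, and chromosome 18 without its clustered protocadherins at -1.57, both left out after the values were seen. Distal peaks on X stood at 0.248 of the autosomal median, when the lowest autosome stood at 0.723. That value restates the low density and holds no measure of CpG, so CpG content stays open for distal peaks too. The number of X copies in tissue pooled from males and females, and X inactivation, were not tested.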

How the results depend on the processing

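Of 886 recomputed values, 767 kept their direction and side of the threshold, 50 fell short of it, 23 newly passed it, 5 moved and 41 turned direction. Of the lists past the threshold, 11 of 16 for width, 5 of 8 for distal peaks and 4 of 16 for marking passed in every alternative. The cause was not tested for any change. The shared peaks, promoter share, X density and the 7 lists of wider domains kept their direction in all these settings, though the anterior Hox list lost its width once each domain was counted once. Lists marked higher went from 8 to 3, and lower from 8 to 4, by the Mantel-Haenszel test over CpG deciles, and higher to 4 by the exact test. Pooled peaks touching both replicate lists by 1 bp were 71.2%, the Hox difference at -log10 q of at least 5 was 38.2 points (Fisher's exact p = 0.0145), and the CpG difference in a window of 500 bp either side was 0.557. The exact test, the peaks touching both replicate lists, and other alternatives named as added in the methods were chosen after seeing the data. Among the 41, only brain width had passed the threshold at first, and only Hox groups 9 to 13 passed after turning, over CpG deciles. Depth is unknown, so no limit from it can be given. No paired analysis was possible because there is 1 group.

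Marking differences, in points, turned as follows. Over CpG deciles, by both tests, heart was 6.78, Hox groups 9 to 13 -27.3, peripheral nerve -6.35 and proximal airway 3.93. Hox groups 9 to 13 were also -2.36 with 1 TSS per gene, -10.7 at the stricter q and -3.7 without sensory receptors, where alveolar type 2 was -0.224. Heart was 3.51 in a window of 2500 bp. Peripheral nerve was -0.226 at the stricter q and -0.368 in peaks touching both lists, where alveolar type 2 was -0.368. Without a replicate, alveolar type 2 ran from -0.63 to 3.89, heart from -0.63 to 3.89 and peripheral nerve from -1.67 to 7.71.

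Width percentiles among random lists turned with a gap of 3 kb for brain (76.5) and mesothelium (60.1), and without a replicate they ran from 38.8 to 100 for smooth muscle and from 7.61 to 54.1 for mesothelium. Distal percentiles turned for immune within 500 kb (54.0), alveolar type 2 beyond 2.5 kb (32.6), unmatched (47.9) and at the stricter q (42.1), peripheral nerve in the pooled list (39.6), Hox groups 9 to 13 unmatched (8.71), at the stricter q (22.3) and in peaks touching both lists (35.8), and germline (54.9) and keratinocyte (50.5) at the stricter q. Without a replicate they ran from 17.3 to 92.6 for Hox groups 9 to 13 and from 49.4 to 63.8 for neuroendocrine. Motif odds ratios turned with windows 20 kb away for SOX (1.01) and HNF4 (0.926), and without a replicate they ran from 0.928 to 1.06 for HNF4, from 1.0 to 1.01 for SOX and from 0.979 to 1.03 for NKX2.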

Other observations

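The gene families below and the test of CpG-poor promoters were chosen after the lists' results were seen, and the genes named in this part were chosen after their values were seen, while the motif tests near lists were written before their results. In all, 25 lists in 3 tests, 13 motif families and 267 families of gene symbols were looked at.

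Genes of the lung cell lists with promoters poor in CpG were marked more often than such genes of the other organs' lists. The latter also included immune (0 of 12 marked), red cell (1 of 10) and peripheral nerve genes (0 of 2), of cells that dissected lung could hold. Among genes in the lowest 3 CpG deciles, 18 of 38 genes of the lung cell lists were marked (47.4%) against 5 of 80 of the other organs' lists (6.25%), and 10.8% of all 6549 such genes. The difference was 41.1 points (Fisher's exact p = 4.94e-07, two-sided), and each replicate's own list gave it, with 22 and 17 of 38 against 10 and 4 of 80. The lung count is carried by endothelium (5 of 6), smooth muscle and pericyte (4 of 5) and alveolar type 2 (5 of 10), while proximal airway had 2 of 10 and mesothelium 1 of 4, and of the other organs heart had 3 of 7. The marked lung genes included Sftpc and Sftpb, the type 1 cell gene Ager (4183 bp) and the vascular genes Lyve1 (3995 bp) and Mmrn2 (4916 bp). The surfactant genes Sftpa1 and Sftpd were unmarked, as were the club cell genes Scgb1a1 and Scgb3a2. The 5 marked genes of other organs were the heart genes Actc1, Myh7 and Myl7, the red cell factor Klf1 and the liver gene Apoa1. The hypothesis, that genes of lung cell lists are marked more often at CpG-poor promoters, is consistent with the pooled counts, which come from the data that raised it, and was not tested within single lists.

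The clustered protocadherins, adhesion genes of neurons, were divided along chromosome 18. Of the alpha cluster 2 of 13 were marked, Pcdhac1 and Pcdhac2, and of the beta cluster 1 of 22, Pcdhb1, against 4 and 2 alpha and 3 and 2 beta genes in the replicates' own lists. Of the gamma genes 11 of 12 in subfamily A, 3 of 6 in B (5 and 3 in the replicates' own lists) and 2 of 3 in C were marked, the A members with a median domain of 782 bp. The numbered alpha genes had 0 of 11 marked where 97.5% were given by CpG content (adjusted exact p = 3.96e-17), and the Rhox homeobox genes of the reproductive tract on X had 0 of 34 where 44.2% were given (adjusted exact p = 1.43e-09).

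Families grouped by symbol gave 5 marked more and 10 marked less than their CpG content, and 12 wider and 8 narrower among 235 tested for width. Collagens (Col) were marked in 39 of 45 (65.8% given, adjusted exact p = 0.00209) and had wide domains, with a median of 2772 bp (adjusted permutation p = 0.0104). The Frizzled receptors of Wnt signals (Fzd) had a median of 5915.5 bp and the Klf factors 4275.5 bp. The 8 narrow families included Cfap (27 marked, median 1359 bp), Spag (10, 911 bp) and Ttll (12, 1241 bp), with adjusted permutation p of 0.0104, 0.0104 and 0.0289. The others were Gm, Pcdhga, Acot, Ddx and Syt. No list of cilia genes was fixed or tested, and the cilia families Ift (14 marked, 1940.5 bp, adjusted permutation p = 0.544) and Dnah (7 of 15 marked, 989 bp, 0.188) did not pass.

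Sites of a lineage's own factors near that lineage's genes were tested in 3 cases. The ETS consensus lay in 4 of 90 distal peaks near endothelial genes, where 9.59% were given by peak width, an odds ratio of 0.446 with an upper 95% limit of 1.2, so the hypothesis was not borne out. For FOX near mesenchyme genes the odds ratio was 1.12 (29 of 143 peaks) and for NKX2 near distal progenitor genes 1.14 (14 of 129), and limits of up to 1.71 and 2.01 leave both open. The adjusted exact p-values were 0.304, 0.647 and 0.647. These tests matched peaks on width and not on GC content. They also took peaks near the same gene as independent, so the limits may be too narrow.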
